A study of Danio rerio with 4 samples.

How the data were processed

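RNA sequencing libraries were made with a TruSeq kit from centroacinar cells (CAC) and non-centroacinar cells (non-CAC), which had been separated by fluorescence-activated cell sorting from dissociated pancreas of adult zebrafish of the AB strain, per the labels' protocols. There were 4 libraries, 1 per group in each of 2 replicates. The sample descriptions place both libraries of a replicate in the same table, so the replicate numbers pair the libraries and each table is a separate within-replicate comparison. The labels do not say whether the replicates came from separate groups of fish, so spread between them may be technical.

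The authors deposited 2 lists of genes and no value per library in those lists. RSEM and the assembly names Zv9 and danRer7 (2 names of one zebrafish assembly) appear without a version or a role in the submitters' processing notes. The model that gave the posterior probabilities is not given in the sources used here. Per the file headers, each row holds an Ensembl gene identifier, a gene name, a locus, the posterior probabilities of equal and of differential expression as fractions between 0 and 1, a posterior fold and an uncorrected fold. Both deposited fold columns are linear ratios between the libraries of a replicate. The headers do not say which population is the numerator. Sides are therefore given as ratio below 1 or above 1, and the value range of the files was not used to assign a population to a side. Every listed gene had a deposited posterior probability of difference of at least 0.99, so genes that did not pass are not seen here and an absent gene may have been similar, too low to call or changed by less than the table could call. Depth per library is unknown, and neither a counting interval for a gene nor a limit of detection could be given. Loci are printed as in the files, with Zv9 taken as their assembly from the submitters' processing notes; 335 of 1812 rows in replicate 1 and 168 of 1560 in replicate 2 had no readable locus.

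Before the data were examined, 26 gene lists (pathways, pancreatic cell types, markers of other cell types, stress, cell cycle), the rule for the genes named in the text and the alternatives to be tried were fixed. The plan foresaw a count test if the files held counts, and otherwise a comparison of the lists. The second form was used. It had been written for the direction CAC over non-CAC, and was applied to the sides of the ratio in its place. The main result was the number of genes listed in both tables, at least 2-fold from 1 and on the same side in both. The posterior fold was used throughout, on a log2 scale. No pseudocount, minimum value or matching on mean expression could be applied, because the tables hold no levels.

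The named genes were the 10 lowest and 10 highest mean log2 ratios of the replicates among same-side genes with a gene symbol, up to 4 same-side members of each list, and 28 genes named whatever their values. List members were ranked by the size of the mean log2 ratio, since the planned ranking by level could not be made. List members were matched by exact, case-sensitive symbol, from the file or through the identifier in a table of Ensembl gene names, in which 2048 of the 3020 distinct identifiers were found. The ribosomal protein and mitochondrial lists were matched by the start of the symbol. For each list with at least 3 listed members in a table, its median log2 ratio was set against 10000 random lists of the same size drawn from that table. This places a list among the listed genes of 2 libraries and is not a replicate test. Each table has 1 library per group, so no p-value was computed within it.

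With the replicate as a block, limma's moderated test was run on the within-replicate log2 ratios of the genes in both tables, with Benjamini-Hochberg adjustment at 0.05. This had been set before the data were examined. These genes had been selected for large ratios in both tables, so its p-values carry that selection. Tested on simulated data with the 352 shared genes, of which 200 were shifted by 4 on the log2 scale, it recovered 59% with 3 false calls. The simulation gave all genes the same spread (a standard deviation of 2.20) and put unshifted genes at 0. Real genes differ in spread, such as 0.0044 for scpp6 and 12.8 for zp2.5, and no listed ratio lies near 1. The 59% therefore does not give the power of the test on these data. The random-list step was tested on 50 simulated lists of 10 genes per table with 9 members below 1. It placed 49 under the fifth percentile in replicate 1 and 13 in replicate 2, so it had little power in replicate 2, where most genes lie below 1.

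Genes whose uncorrected and posterior fold differed by over 10 times are called floor genes. The split was clean, because no factor lay between 9.48 and 138.4 in replicate 1 or between 2.39 and 79.7 in replicate 2. Intervals on shares of genes are exact Clopper-Pearson intervals at 95% that cover counting of genes only. Alternatives were a 4-fold threshold, list membership alone, a posterior probability of no difference under 0.001, centring on the table median, the replicate block and each replicate alone. The uncorrected fold, removal of floor genes and removal of an oocyte list were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.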

Results

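Gene expression was compared between sorted centroacinar cells and sorted non-centroacinar cells of the adult zebrafish pancreas. Centroacinar cells lie at the ends of the pancreatic ducts, within the acini. The design asks which genes differ in expression between them and the other sorted cells. Each group had 2 libraries, and each replicate pair has its own table of genes called different by the authors. The table of replicate 1 lists 1812 genes and that of replicate 2 lists 1560 genes. Total counts per library are unknown. The ratio in each table is between the libraries of a pair, and the headers do not name its numerator, so genes are described as lying below 1 or above 1.

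Of the fixed gene lists, 7 had at least 3 members below 1 in both replicates. These were ductal and centroacinar markers (12), pancreas transcription factors (7), epithelial junctions (6), ion transport (5), and the Notch pathway, growth factor receptor feedback and the immediate-early and dissociation response (4 each). The lists overlap, with 32 distinct genes in all, and 4 of the 7 transcription factor genes, 3 of the 6 junction genes and 3 of the 5 transport genes are also ductal and centroacinar members. These genes included her15.1, her15.2 and her6, which encode transcriptional repressors of the Hes family induced by Notch, the chloride channel gene cftr, and the transcription factor genes nkx6.1, pdx1, onecut1 and foxa2. Genes of the digestive enzymes made by acinar cells lay above 1, in replicate 2. Of 3020 distinct genes, 352 were in both tables. Of these, 216 lay below 1 in both and 115 lay above 1 in both, each at least 2-fold from 1, as was every listed gene. The other 21 lay on opposite sides, 19 of them above 1 in replicate 1 and below 1 in replicate 2. The same-side share was 94.0% (95% interval 91.0% to 96.3%, counting of genes only), where sides independent of each other would give 54.0%.

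With the replicate as a block, limma called 4 genes below 1 and 0 above 1 at a Benjamini-Hochberg adjusted p of 0.05, and 104 and 93 at an unadjusted p of 0.05. The limma counts do not measure whether sides repeat. By the same-side share above, most shared genes kept their side, while the size of single ratios appeared to repeat less well. Across the 216 genes below 1 in both, Pearson's r between the replicates' log2 ratios was 0.45 and Spearman's rho 0.51. Across the 115 genes above 1 in both, they were -0.18 and -0.11. These are correlations across genes, which are not independent replicates. Of the 115, only 38 were floor genes in neither table, and the ratios of the others depend on the fold column used. Each table also lists only ratios well away from 1, which narrows the range that the correlations cover.

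**Figure D1:**
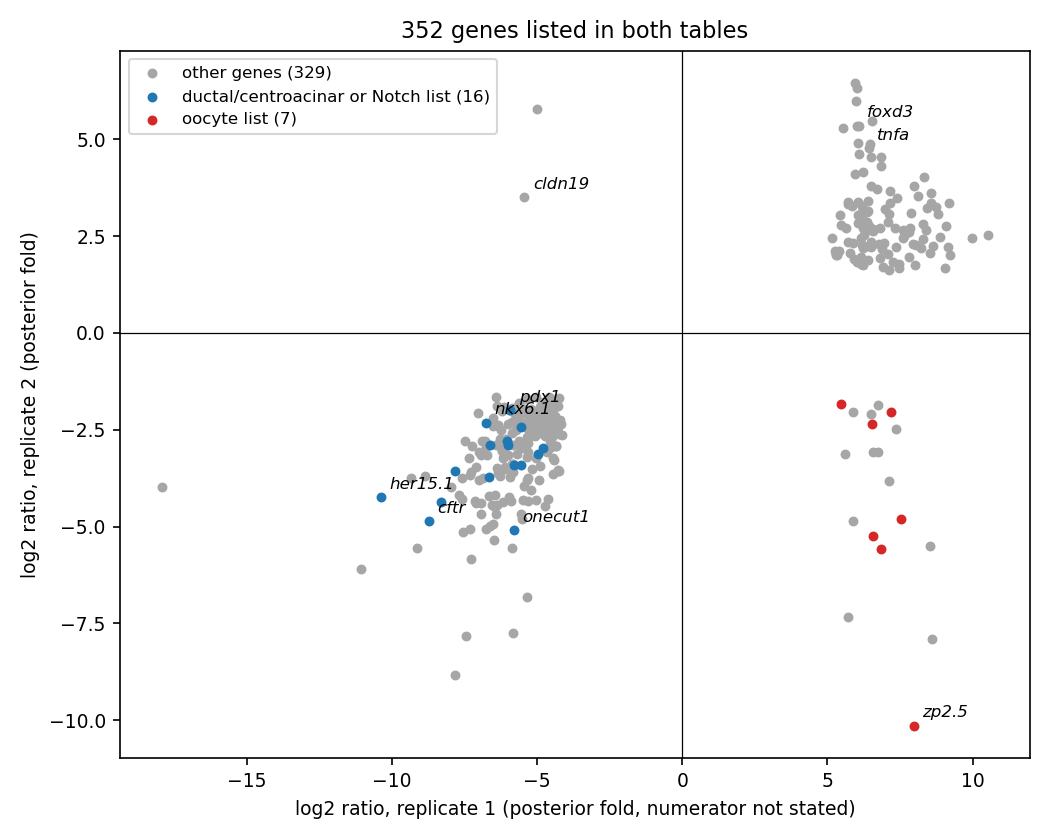
Each point is 1 of the 352 genes listed in both tables, with the log2 posterior ratio of replicate 1 on the x axis and of replicate 2 on the y axis; colours mark the ductal/centroacinar or Notch lists (16 genes) and an oocyte list assembled after seeing the data (7 genes). The 16 blue genes all lie below 1 in both replicates (lower left), and the 7 oocyte genes lie at the lower right, above 1 in replicate 1 and below 1 in replicate 2.

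Among the genes farthest below 1, the authors' deposited tables gave clcn1b, a chloride channel gene (Zv9 chromosome 16, 19539814 to 19603548), a log2 ratio of -11.07 in replicate 1 and -6.11 in replicate 2. The Notch target her15.1 (chromosome 11, 43089904 to 43091345) was at -10.38 and -4.25 in the authors' deposited tables, and the neighbouring copy her15.2 at -8.32 and -4.37. Reads may be split between these closely related copies, so their separate values are uncertain. In the same deposited tables, cftr (chromosome 18, 20457800 to 20503521) was at -8.74 and -4.86, the water channel gene aqp8a.1 at -8.88 and -3.70, and the claudin gene cldn29 at -9.15 and -5.54. The remaining 4 of the 10 lowest were MYADM, tmem196b, cbln17 and col28a1, with tmem196b at -9.33 and -3.74 in the authors' deposited tables.

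Among the genes farthest above 1, the authors' deposited tables gave the potassium channel gene KCNH1 9.97 and 2.45, and the chemokine receptor gene cxcr3.2 6.55 and 5.46, as log2 ratios in replicates 1 and 2. The neural crest transcription factor gene foxd3 was at 6.08 and 5.35 in the authors' deposited tables, and pou3f2, a neural transcription factor gene, at 6.84 and 4.54. The others were scpp6, mtnr1ba, MFAP4 and the Pim-related kinase genes pimr52, pimr57 and pimr54. The last 4 belong to families with many similar copies, so reads may be shared among copies. All of these 10 genes were floor genes in replicate 1, where the posterior and the uncorrected fold differ by over 138 times, and foxd3 and scpp6 were in replicate 2 as well, so their values and order depend on the fold column used. Of the 10 lowest, none was a floor gene in replicate 1, and cldn29, MYADM, cbln17 and col28a1 were in replicate 2.

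Of the ductal and centroacinar list, 13 members were listed in replicate 1, all 13 below 1, and 20 in replicate 2, 19 of them below 1. The exception was the keratin gene krt18b, at a log2 ratio of 1.93 in the authors' deposited table of replicate 2. In the deposited tables, 12 members lay below 1 in both, among them krt94 at -7.85 and -3.57 and slc4a4b, a sodium bicarbonate cotransporter gene, at -6.66 and -3.71. The authors' deposited tables placed nkx6.1 (chromosome 21, 17886032 to 17888943) at -6.76 and -2.32, pdx1 at -5.93 and -1.99, and hnf1ba at -4.82 and -2.98. The gene sox9b, a regulator of ductal progenitors, was listed in replicate 2 alone, at -4.41 in the authors' deposited table. The list's median was at or above those of 2 of 10000 random lists in replicate 1 and of 235 in replicate 2.

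Of the Notch list, 4 members lay below 1 in both replicates, namely her15.1, her15.2, her6 and the receptor gene notch3. In the authors' deposited tables, her6 was at -6.63 and -2.88 and notch3 at -6.02 and -2.79. The receptor gene notch1a and the feedback gene nrarpb were listed in replicate 2 alone, at -1.70 and -1.68 in the authors' deposited table. The ligand genes dlb, jag2a and dld were listed in replicate 1 alone and above 1, at ratios of 68.8, 82.5 and 267 in the authors' deposited table. Of these, dlb and jag2a were floor genes, so their ratios depend on the fold column used. The median was at or above those of 67 random lists in replicate 1 and of 903 in replicate 2, both of 10000. The Notch list thus did not clearly stand apart in replicate 2, where this step had little power.

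Pancreas transcription factor genes lay mostly below 1, with 9 of 10 listed members in each replicate and 7 in both. Besides those named, the authors' deposited tables gave foxa2 -6.34 and -3.62, onecut1 -5.82 and -5.10, sox11a -5.32 and -4.33 and nkx2.2a -6.42 and -2.89. The acinar regulator ptf1a was the exception in replicate 2, at 2.74 in the authors' deposited table, and onecutl was the exception in replicate 1, at 6.35. The list's median was at or above those of 4 random lists in replicate 1 and of 460 in replicate 2.

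Genes of epithelial junctions and of bicarbonate, ion and water transport lay mostly on the same side. All 13 listed junction members of replicate 2 and 7 of 8 in replicate 1 lay below 1, and 6 did so in both. The claudin genes cldn7b (-6.86 and -3.75), cldnb (-5.78 and -3.42), cldnc (-5.56 and -3.42) and cldn15a (-6.27 and -2.73) were among them in the authors' deposited tables. Of the transport list, 5 members lay below 1 in both, with the carbonic anhydrase gene ca4b at -5.18 and -3.51 in the authors' deposited tables. Exceptions above 1 were oclnb, aqp1a.1 and ca4a in replicate 1, all floor genes, and aqp12 in replicate 2. The median of the junction list was at or above those of 16 and 561 of 10000 random lists in replicates 1 and 2, and that of the transport list at or above those of 60 and 236. In replicate 2, all 18 listed egg coat genes lay on this side as well, and 1 junction member, cldnd, is also an oocyte gene. No gene of the oocyte list was among the 331 same-side genes, so the counts of 216 and 115 do not include them.

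Of the list of growth factor receptors and their feedback, erbb3a, fgfr3, dusp4 and hbegfa lay below 1 in both replicates. In the authors' deposited tables, erbb3a, a neuregulin receptor gene, was at -5.47 and -3.96, and fgfr3 at -4.80 and -2.17. The exception was erbb4a, above 1 in replicate 1 at 5.65 in the authors' deposited table. The list's median was at or above those of 438 of 10000 random lists in replicate 1 and of 3494 in replicate 2, so it did not stand apart in replicate 2. The Wnt antagonist gene frzb was at -6.52 and -2.40 in the authors' deposited tables, the only member of the Wnt list in both. Of the Hippo-YAP list only f3b, the tissue factor gene, was in both deposited tables, at -5.88 and -2.29. No member of the BMP and TGF-beta list or of the retinoic acid list was in both. Of the retinoic acid list, the authors' deposited table of replicate 2 alone held rdh10a, at -1.86, and rbp7, a floor gene, at 6.73. Neither aldh1a2 nor aldh1a3, which encode enzymes of retinoic acid synthesis, was in either table.

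Acinar digestive enzyme and secretory genes had more members above 1 in replicate 2 than any other of the fixed lists, with 31 listed and all 31 above 1. Their ratios ran from 4.35 to 11.7 with a median of 6.38. In the authors' deposited table of replicate 2, the elastase gene ela2l was at a ratio of 11.7, the carboxypeptidase gene cpa5 at 9.39, the amylase gene amy2a at 7.49, the trypsin gene try (prss1 in the name table) at 6.57 and the chymotrypsinogen gene ctrb1 at 5.62. The list's median was at or above those of 9998 of 10000 random lists. None of the 31 was listed in replicate 1, where the smallest ratio above 1 was 35.3. Only cuzd1.1 of this list was listed there, at a log2 ratio of 7.12 in the authors' deposited table. The acinar result thus rests on 1 pair of libraries.

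Endocrine islet genes fell on both sides. The insulin gene ins lay above 1 in replicate 2, at a ratio of 3.28 in the authors' deposited table, and was not listed in replicate 1. The authors' deposited tables placed neurog3 below 1 at -6.95 in replicate 1 alone, and rfx6 above 1 at 9.03 in replicate 1 alone, both of them floor genes. Of the 4 listed members in replicate 1, 2 lay on each side, and in replicate 2 4 of 5 lay above 1. Neither gcga nor sst2 was in either table.

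Leukocyte markers lay mostly above 1, with 8 of 9 listed members in replicate 1 and 14 of 16 in replicate 2, although only tnfa and rag1 did so in both. The list's median was at or above those of 6328 of 10000 random lists in replicate 1 and of 9459 in replicate 2, so it did not stand apart in replicate 1, where most listed genes lay above 1. In the authors' deposited tables, the cytokine gene tnfa was at 6.42 and 4.78, and rag1, of lymphocyte receptor rearrangement, at 6.18 and 1.85. Both were floor genes in replicate 1, and tnfa in replicate 2 as well. Of the other leukocyte members above 1 in replicate 1, wasa, lck, marco and ighm were floor genes, and only lyz and cd4 were not. The pan-leukocyte gene ptprc was at a ratio of 4.22 in replicate 2 in the authors' deposited table, on the side of the acinar genes. Exceptions below 1 were cd9b, at -7.00 and -3.80 in the deposited tables, and ighd, a floor gene, in replicate 2. Of the neural and glial list, foxd3 and elavl3 lay above 1 in both, and of the cilia list only dnah9 did. Endothelial markers were listed almost entirely in replicate 1, 4 above 1 and 2 below, and kdrl was in neither table. Of those above 1, aqp1a.1, etv2 and mrc1a were floor genes and flt1 was not. Mesenchymal markers lay on both sides, 5 below and 4 above 1 in replicate 2. Hepatocyte markers, with 2 above 1 in each replicate and none in both, did not include fabp10a. Erythrocyte markers were few, with 1 listed in replicate 1 and 3 in replicate 2, and adipose and mesothelial markers likewise, with 1 and 2. The one intestinal member was aqp8a.1, and of the endoplasmic reticulum list pdia2 lay above 1 in replicate 2, at a log2 ratio of 2.45 in the authors' deposited table. A second member of that list, also above 1, is an elastase gene that had been placed there under a clone name.

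Immediate-early and dissociation response genes lay below 1 wherever listed, 5 of 5 in each replicate and 4 in both. In the authors' deposited tables, gadd45bb was at -6.72 and -3.14, nr4a2b at -5.82 and -2.90 and btg2 at -5.63 and -1.80. The list's median was at or above those of 134 of 10000 random lists in replicate 1 and of 5475 in replicate 2, so it did not stand apart in replicate 2. These genes lie on the same side as the ductal and Notch genes, so a difference in handling between the sorted cells was not separated from a difference in cell type. Of the cell cycle list only ccnd2a was listed, at -4.39 in replicate 1 in the authors' deposited table. No ribosomal protein gene and no gene of the mitochondrial electron transport list was in either table.

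**Figure D2:**
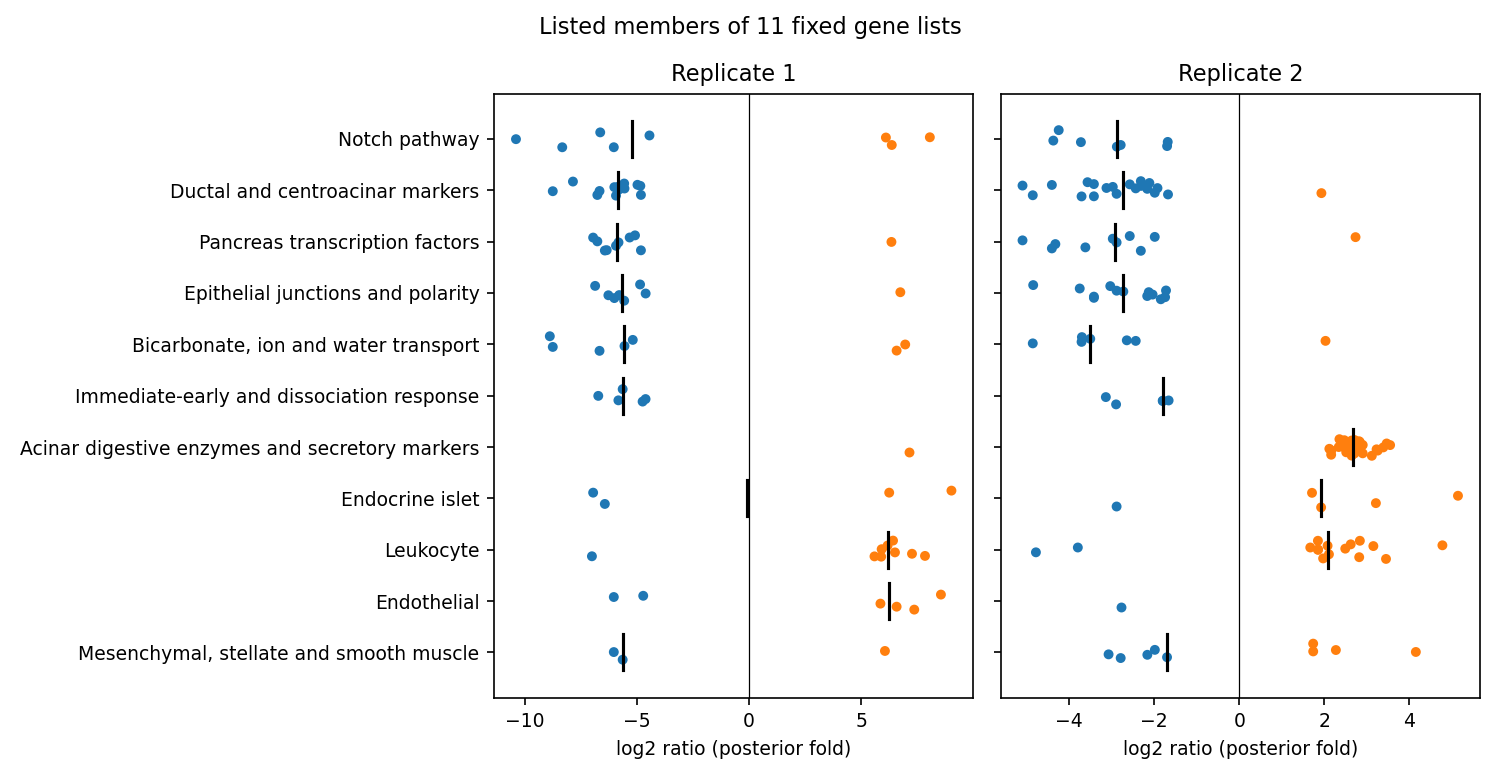
Log2 posterior ratios (x axis) of the listed members of 11 of the fixed gene lists (rows) in replicate 1 and replicate 2, blue below 1 and orange above 1, with a bar at the median where at least 3 members were listed; the x axes differ in range. Ductal, Notch, transcription factor, junction and transport genes lie mostly below 1 in both, and the 31 acinar genes of replicate 2 lie between log2 ratios of 2.12 and 3.55.

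Of the 28 genes named whatever their values, 7 were in both tables, nkx6.1, pdx1, her15.1, her6, notch3, cftr and hnf1ba, and all lay below 1 in both. Another 10 were in replicate 2 alone and 0 in replicate 1 alone. The 11 in neither were her9, notch1b, notch2, jag1b, jag2b, aldh1a2, aldh1a3, gcga, sst2, fabp10a and kdrl.

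The tables differed in scale and balance. In replicate 1, 1206 genes (66.6%) lay above 1 and 606 (33.4%) below, and in replicate 2, 670 (42.9%) above and 890 (57.1%) below. The median log2 ratio above 1 was 6.55 in replicate 1 and 2.61 in replicate 2, and below 1 it was -5.10 and -2.81. The listed ratio nearest to 1 was 35.3 above and 0.0571 below in replicate 1, against 2.98 and 0.325 in replicate 2. Of the 216 genes below 1 in both, 212 were farther from 1 in replicate 1, and of the 115 above 1 in both, 113 were. These nearest ratios were observed among genes called by posterior probability, and no fold rule is stated. The listed ranges nearly fix this outcome. Every listed ratio was at least 35.3 or at most 0.0571 in replicate 1, against 2.98 and 0.325 in replicate 2. These counts and the medians therefore do not show a difference in scale beyond the listed ranges. Floor genes made up 63.6% of the genes above 1 in replicate 1 (767 genes) and 8.58% of those below (52 genes). In replicate 2 they were 65 of the 670 above and 98 of the 890 below. Without floor genes, the count above 1 in both fell from 115 to 38 and the count below 1 in both from 216 to 200. Genes common to both tables on the high side were thus mostly ones with a floor value in at least 1 table.

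**Figure D3:**
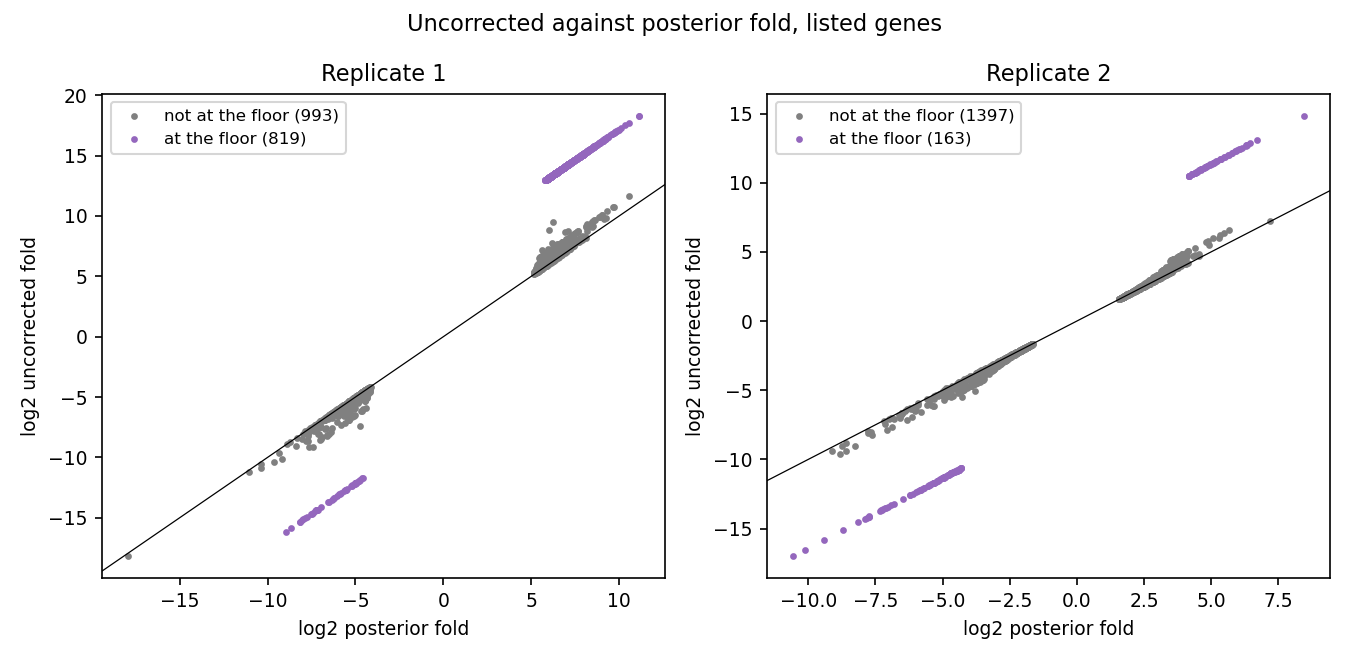
Log2 uncorrected fold (y axis) against log2 posterior fold (x axis) for each listed gene of replicate 1 and replicate 2, as the authors deposited them; the line marks equal values, and purple marks floor genes, whose 2 folds differ by over 10 times. In replicate 1, 819 genes are at the floor, most of them above 1, against 163 in replicate 2.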

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

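The same-side counts (216 below 1 and 115 above 1 in both replicates) kept within 1.5 times at a 4-fold threshold (183 and 99). List membership alone, the uncorrected fold and removal of the oocyte list could not move them. Every listed ratio was already over 2-fold from 1, the fold columns never differed in side, and no oocyte gene was among the same-side genes. A posterior probability of no difference under 0.001 in both tables gave 125 and 33 genes, and centring each table on its median gave 101 and 44. Centring subtracts the median of listed genes only, 6.02 in replicate 1 and -1.90 in replicate 2, and so redraws the sides. Without floor genes 38 lay above 1 in both, and the same-side share was 96.7% in place of 94.0%. With the replicate block, limma called 4 genes below 1 and 0 above 1 (104 and 93 at an unadjusted p of 0.05). Its construction divides by the spread between replicates, and the ratios listed in replicate 1 start farther from 1 than those of replicate 2. Each table alone gave 606 to 890 genes below 1 and 670 to 1206 above. At least 3 members lay below 1 in both for 7 fixed lists (8 to 9 in a single table, 4 after centring) and above 1 in both for 0 (5 in each single table). With the uncorrected fold, 11 of the 52 named genes in both tables moved beyond the spread between replicates. That spread is each gene's own, so a gene with a wide spread can shift far and not be counted. Among those not counted, the mean log2 ratio of KCNH1 went from 6.21 to 9.81 and that of pimr54 from 5.69 to 9.29. The count of 11 thus understates the dependence on the fold column. Leaving out a replicate is no test of a single gene here, because with 2 replicates either value lies within their spread by construction, and these genes had been chosen for the same side in both. Settings that need levels (pseudocounts, a minimum value, size factors) had no value to act on and were not run. Depth is unknown, and the smallest ratio above 1 that a table listed (35.3 in replicate 1, 2.98 in replicate 2) limits what absence from a table can show.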

Other observations

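All tests of this part were chosen after the pattern they address had been seen, and 2 of them, on floor genes and on acinar genes, before their own result, although the reading of the acinar test was revised after it. The following gene groups were picked after their values were seen. Pim-related kinase genes (pimr), a family with many copies, lay above 1 in all of their listings, 16 in replicate 1 (11 of them floor genes) and 45 in replicate 2, with 11 in both. Genes of the hoxC clusters on chromosomes 23 and 11, which set position along the body axis, lay above 1 in 7 of 7 listings in replicate 1 (5 of them floor genes), where 66.6% of all listed genes did. They did so in 2 of 2 listings in replicate 2, and the authors' deposited tables gave hoxc5a 6.01 and 5.33 and hoxc8a 6.23 and 2.72. Below 1 in both lay the tachykinin receptor genes TACR2 (-7.12 and -3.47) and TACR3 (-6.93 and -4.67) and the chemokine genes ccl20 (-5.33 and -3.08), cxcl12b (-5.86 and -1.93) and ccl19a.1 (-7.04 and -2.08) in the authors' deposited tables. Of these, hoxc5a was a floor gene in replicate 1 and TACR3 in replicate 2. Another chemokine gene, ccl34a.4, lay above 1 in replicate 2, at 3.29 in the authors' deposited table. Symbols beginning with znf lay below 1 in 18 of 18 listings in replicate 2, where 57.1% of all listed genes did. In replicate 1 they did so in 3 of 7. Several of the listings in replicate 2 share the name ZNF251, so the 18 cannot be counted as unrelated genes. Sharing of reads among these copies was not tested.

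Which population is the numerator is a hypothesis here. If the ratio is non-CAC over CAC in both tables, ductal, centroacinar and Notch genes are expected below 1 and acinar genes above. In replicate 2, 95% of the 20 listed ductal and centroacinar genes and 7 of 7 Notch genes lay below 1, and 0 of 31 acinar genes did, which is consistent with that reading. In replicate 1, 13 of 13 ductal and centroacinar genes and 5 of 8 Notch genes lay below 1. The reading rests on knowledge of the markers and not on a label, so these genes cannot serve as evidence for both the direction and a finding, and a swap of both libraries within a pair would give the opposite reading.

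Genes of the egg coat (zona pellucida proteins), which are made by oocytes, lay on opposite sides in the replicates: 7 of 7 above 1 in replicate 1, and 18 of 18 below 1 in replicate 2. Their median log2 ratios in the authors' deposited tables were 7.20 and -4.97. RNA of oocytes in 1 library of each pair is a candidate explanation. Its test used oocyte genes other than egg coat genes, of which no value had been seen when they were listed. They lay on the egg coat side in 5 of 5 listings (100%). These were foxr1, dnd and pou5f1 below 1 in replicate 2, and lhx8a and slbp2 above 1 in replicate 1. Of them, foxr1 and lhx8a were floor genes. Of all listed genes, 57.1% lay below 1 in replicate 2 and 66.6% above 1 in replicate 1, so 5 listings are too few to decide. None of the 5 genes was in both tables, so none of them shows a change of side. In replicate 2 1 of 18 egg coat genes was a floor gene, but in replicate 1 6 of 7 were, so a low and uncertain signal in replicate 1 stays open. A stable difference between the sorted populations stays open too, although 100% of the 5 egg coat genes in both tables changed side, because all 5 were floor genes in replicate 1 and the change of side is the pattern itself. The oocyte genes dvr1 (5.46 and -1.82) and patl2 (6.53 and -2.35) changed side in the authors' deposited tables without being floor genes in either, but both were picked because of their sides. Also open is a carry-over of ovary tissue at dissection against another origin. The oocyte list accounts for 7 of the 21 genes on opposite sides and for 0 of the 331 on the same side.

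Replicate 2 listed on the same side 35.6% of the 606 genes below 1 in replicate 1 (95% interval 31.8% to 39.6%), against 9.54% of the 1206 above 1 (7.94% to 11.3%). Floor genes, as defined here, are argued against as the whole cause. Among genes not at the floor the low-side share was 4.46 times the high-side share, 38.6% of 554 against 8.66% of 439, with intervals that did not overlap. The genes left after this cut still had folds that differed by up to 9.48 times in replicate 1. A low signal short of the floor was therefore not tested and stays open. Among floor genes the order was the opposite, 2 of 52 below 1 against 77 of 767 above, a ratio of shares of 0.383 with overlapping intervals. Differences in depth, in cell composition of the non-CAC sort and in the preparation of the pairs stay open, because the tables hold no levels, and no biological explanation was tested.

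The 31 acinar genes above 1 in replicate 2 were all absent from replicate 1. A larger fold needed for listing in replicate 1, where every ratio above 1 was 35.3 or more, might be the cause. Among the 337 other genes with ratios in the acinar range in replicate 2, 20.5% (16.3% to 25.2%) were listed above 1 in replicate 1, against 0 of 31 (Fisher's exact test, two-sided, p = 0.00267), a share above the 5% set as a bound. That bound was wrong, because it took genes with like ratios in replicate 2 to have like ratios in replicate 1. The 69 other genes listed had ratios of at least 35.3 there, and 48 of them were floor genes, whereas acinar genes with their ratios of replicate 2, up to 11.7, would all have stayed under 35.3. A larger fold needed for listing, with unchanged acinar ratios, cannot be told apart from a smaller acinar difference in replicate 1. Genes that are not listed there have no value. Acinar genes are regulated together, so the p-value treats as independent what is not.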
